A study of Mus musculus with 45 samples.

How the data were processed

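RNA of mouse lung and liver was hybridised to Agilent whole-genome arrays against a universal mouse reference RNA, with the sample in Cy5, the reference in Cy3 and no dye swap. Lung microRNA was hybridised to Agilent microRNA arrays in Cy3 alone. The input was 250 ng of RNA for mRNA and 100 ng for microRNA. Lung mRNA was measured in 8 control arrays and 7 arrays at each dose, lung microRNA in 3 control arrays and 5 at each dose, and liver mRNA in 5 control arrays and 5 at 300 mg/kg.

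Per the file headers, the authors read the lung mRNA arrays with Agilent Feature Extraction 9.5.3.1, the liver arrays with 10.1.1.1 and the microRNA arrays with 10.7.3.1, whereas the labels name 9.5.3.1 for all. The deposited scanner files give the intensity of each spot and of its local background. The lung files hold mean and median signals, and the liver files hold median signals only. The deposited log10 ratio of Cy5 over Cy3 had been background-subtracted and dye-normalized by the scanner software. The deposited flags, other than these measurements, mark spots that are well above background, non-uniform or saturated and give the type of each control spot. The deposited microRNA intensity had been background-subtracted by the scanner software and not scaled between arrays, so that dim spots lie below 0. The deposited series values are log2 ratios centred near 0 for mRNA and log2 intensities with nearly the same distribution on every array for microRNA, and no header states how the authors made them.

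The mRNA intensities were processed again in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. Background was corrected with normexp and an offset of 50, and the log2 ratio of Cy5 over Cy3 was normalized by loess within each array. The lung used mean signals, and the liver used median signals because its files hold no others. Control spots and non-uniform spots were left out (356 spots on the lung arrays, 72 on the liver arrays). On 4 lung arrays such spots had disturbed the normexp fit, so they were left out of it as well before any gene was tested. A probe was kept if its Cy5 signal was well above background on at least as many arrays as the smallest group had. Of 41174 probes 22951 were named through the accession in the file, 6659 through a current gene symbol, 3109 through an older symbol and 8455 by the name in the file. Each gene was represented by its brightest probe, by mean log2 background-corrected Cy5 signal. Probe positions are those of the mm7 build in the files.

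For microRNA the log2 processed intensity was taken relative to the array's 75th percentile over the probes detected on every array, after spots were averaged per probe and probes per microRNA. Signals under a floor of 0.102 of that percentile were set to it. A microRNA was kept if it was detected on at least 3 arrays.

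As a measure of depth, 62.1% to 82.6% of probes were well above background on the lung arrays, 45.1% to 57.7% on the liver arrays and 40.3% to 47.7% of microRNAs were detected. The number of arrays limits the precision. The log ratios correlated across probes with the deposited series values at 0.994 to 0.997 per lung array, 0.993 to 0.995 per liver array and 0.988 to 0.997 per microRNA array, where probes are not independent replicates.

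Each comparison was fitted with limma's lmFit and eBayes, with p adjusted by Benjamini-Hochberg over the genes tested and a threshold of 0.05. All tests were two-sided. The lung fit held 22 arrays in 3 groups, the liver fit 10 arrays, and the difference between tissues 25 arrays in 4 groups with each tissue normalized alone. Where the control group stood above background on no array, a fold written with "at least" is given as well. It compares Cy5 signals after loess and Aquantile, with each control array at the higher of its own signal and the lowest signal well above background. It is another scale than the ratio to the reference, is open to dye bias and can exceed the fold of the ratio. A microRNA change is a bound where arrays of the lower group lay at the floor, and their number is given.

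Before the data were examined, 40 gene lists and 11 microRNA lists, the tests, most alternatives and the rule for naming genes were fixed. The rule names the 8 largest rises and the 8 largest falls among genes past the threshold whose higher group stood above background on all its arrays, 5 each way between the doses and between the tissues. It adds Cyp1a1, Cyp1b1, Nqo1, Cdkn1a, Mdm2 and Ccng1 throughout, Cyp1a2 in liver, and up to 4 members with the smallest p of each list that passed or held at least 3 called members. Some genes that the rule picks are not used here. For microRNA it names 6 each way, or the 5 with the smallest p where fewer than 3 passed, and always the miR-34 forms. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the lists. A count of members adjusted over the list alone is given beside that over all genes.

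The overlap of the doses was compared with 100 simulations of unchanged groups that share the controls, and with the 70 splits of the controls into 4 and 4. The methods were tested on simulated data: with 200 genes changed, a log2 change of 1 was recovered in 95.5% of genes in lung at 300 mg/kg, 97.0% in liver and 97.0% in the difference between tissues. A change of 0.5 was recovered in 95.5%, 50.7% and 62.7%. With 60 microRNAs changed, 95.0% were recovered at a log2 change of 1 and 60.0% at 0.5, and 8.93% of the microRNA calls at 300 mg/kg were false. Each simulation was a single draw of independent normal noise with the same spread in every group. In the real data microRNA controls could vary more than treated arrays, as for miR-150 (SD 0.69 in controls, 0.12 at 300 mg/kg). The microRNA rates may therefore not hold for these arrays.

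Replicate numbers in the titles were examined as a possible pairing. Only control and 150 mg/kg lung arrays of the same number correlated above 0.1 in all 7 pairs (0.11 to 0.52, mean 0.26, against 0.16 for other numbers of the same scan day), and 3 of the 7 were closest to their own number. The replicate number was therefore tried as a block and not used in the results. Slide, scan day and position on the slide were tried as blocks too. Other alternatives changed the background correction, the scaling, the filter, the probe per gene, the arrays used, the variance model and the list test, and left out each array in turn. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.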

Results

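Messenger RNA was profiled in lung and liver, and microRNA in lung, of adult male mice of the hybrid strain B6C3F1 that had received benzo(a)pyrene or only corn oil by gavage. Benzo(a)pyrene is a polycyclic aromatic hydrocarbon formed when organic matter burns, and its metabolites bind DNA. Tissues were taken 4 h after the last of 3 daily doses. The 45 arrays formed 8 groups. Lung mRNA was measured on 8 control arrays, 7 arrays at 150 mg/kg and 7 arrays at 300 mg/kg. Lung microRNA was measured on 3 control arrays and on 5 arrays at each dose. Liver mRNA was measured on 5 control arrays and 5 arrays at 300 mg/kg. Each array was fitted as 1 animal, although the labels state 6 mice per group and 5 per group for microRNA, which the numbers of arrays do not match. Of 41174 mRNA probes, 25556 to 34009 stood well above background on the lung arrays and 18558 to 23757 on the liver arrays. The microRNA arrays detected 262 to 310 microRNAs each, and their brightness at the 75th percentile ranged from 151 to 326 in controls, from 265 to 326 at 150 mg/kg and from 281 to 360 at 300 mg/kg. Control microRNA arrays 1 and 3 were the dimmest. The number of arrays per group limits the precision of every value below, each of which is a log2 change with its standard error and a Benjamini-Hochberg adjusted p from limma.

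The first comparison asked which genes changed in lung at 300 mg/kg. The largest rises were those of genes that the aryl hydrocarbon receptor induces. Cyp1b1, a cytochrome P450 that activates polycyclic hydrocarbons, rose 48.5-fold, from a log ratio to the reference of -1.76 ± 0.20 (SD, n = 8) in controls to 3.84 ± 0.21 (SD, n = 7). Cyp1a1 rose 29.5-fold, Ahrr, which represses the receptor, 24.5-fold, and the quinone reductase Nqo1 21.7-fold. The cell cycle inhibitor Cdkn1a, a target of p53, rose 9.19-fold. In the other direction, markers of B cells, T cells and thymus and genes of the interferon response fell together. Esm1, which is made by endothelial cells, fell by 3.39 on the log2 scale.

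Among 19453 genes tested, 6368 (32.7%) changed at an adjusted p of 0.05 in lung at 300 mg/kg, 2416 of them upward and 3952 downward. Most changes were small, with a median absolute log2 change of 0.30 among the genes that passed. At least 1.5-fold changes were seen in 1062 genes (403 up, 659 down) and at least 2-fold changes in 290 genes (138 up, 152 down). The log2 change was 5.60 ± 0.110 for Cyp1b1 (adjusted p 1.28e-20, chromosome 17, 78002920 to 78002979 in mouse build mm7), although a dimmer probe of the same gene gave 1.25. It was 4.88 ± 0.167 for Cyp1a1 (adjusted p 5.55e-16, chromosome 9, 57731394 to 57731453), 4.44 ± 0.121 for Nqo1 (adjusted p 6.72e-18, chromosome 8, 105988683 to 105988742) and 3.20 ± 0.111 for Cdkn1a (adjusted p 7.14e-16, chromosome 17, 27293819 to 27293878). Esm1 changed by -3.39 ± 0.168 (adjusted p 4.62e-13, chromosome 13, 110373894 to 110373953). The other genes with the largest rises were Srxn1 (3.43 ± 0.128), the heat shock gene Hspa1a (3.33 ± 0.406) and Maff (3.25 ± 0.0882). Other large falls were those of the retinoic acid hydroxylase Cyp26b1 (-2.83 ± 0.406), Rgs3 (-2.40 ± 0.107), the B cell antigen Ms4a1 (-2.24 ± 0.179), Tnfsf10 (-2.15 ± 0.0775), Rsad2 (-2.15 ± 0.107) and Prdm8 (-2.08 ± 0.119). All 7 treated arrays lay beyond the control mean for each of these genes, and the groups overlapped for Hspa1a alone. Dimmer probes of Rgs3 (-0.63 to -0.11), Rsad2 (-0.69 to -0.44) and Prdm8 (-0.20) changed less.

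Of the 40 gene lists fixed before the data were examined, 18 differed from the other genes with a preset correlation between genes, and 10 of these also with an estimated one. Random regroupings of the arrays gave 0 list calls with the estimated correlation and a median of 16 with the preset one, so the lists that hold with the estimated correlation come first. Among aryl hydrocarbon receptor targets, 9 of 15 measured members rose and 1, the receptor gene Ahr itself (-0.54), fell (list adjusted p 7.31e-12, 0.000176 with an estimated correlation; 10 members changed when adjusted over the list alone). Of the NRF2 and glutathione enzymes, which defend against oxidants and electrophiles, 24 of 34 rose and none fell (7.85e-20 and 9.79e-05; 25 when adjusted over the list alone). Examples were Txnrd1 (1.89 ± 0.0673) and Cbr3 (2.09 ± 0.0801). Of 36 p53 targets 25 rose and 2 fell (4.41e-15 and 0.00494; 28 when adjusted over the list alone), with Gdf15 at 2.55 ± 0.157, Sesn2 at 1.39 ± 0.0954, Plk3 at 1.37 ± 0.0898, Mdm2 at 0.71 ± 0.0763 and Ccng1 at 0.70 ± 0.0911. Of 20 immediate early genes 16 rose (1.28e-11 and 0.0169; 16 when adjusted over the list alone), among them Klf4 at 1.89 ± 0.152. Of 16 glucocorticoid response genes 13 rose (1.21e-11 and 0.0236; 15 when adjusted over the list alone), with Tsc22d3 at 2.00 ± 0.207 and Klf9 at 1.53 ± 0.102. Of 20 genes of the endoplasmic reticulum and integrated stress response 14 rose (8.8e-09 and 0.0263; 14 when adjusted over the list alone), with Herpud1 at 1.15 ± 0.091 and Atf4 at 0.91 ± 0.0892.

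Of 25 B cell markers 23 fell in lung at 300 mg/kg, with a median log2 change of -1.10 (1.01e-16, and 0.0236 with an estimated correlation; 23 when adjusted over the list alone). Spib changed by -1.18 ± 0.0804 and the IgM receptor Fcmr by -1.80 ± 0.123. Of 24 T cell markers 18 fell, with a median of -0.60 (2e-11 and 0.0236; 18 when adjusted over the list alone), among them Lck (-1.25 ± 0.0986), Cd3d (-1.09 ± 0.0944) and Cd27 (-0.68 ± 0.058). Of 8 thymus markers 7 fell, with a median of -0.50 (2.7e-05 and 0.0236, and 7 when adjusted over the list alone). The fixed thymus list shares Cd4, Cd8a, Lck, Tcf7 and Themis with the T cell list, so these results are not independent. Of 23 interferon response genes 22 fell, with a median of -0.52 (1.78e-14 and 0.00683; 22 when adjusted over the list alone), among them Rtp4 (-1.08 ± 0.0777).

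Lists that passed only with the preset correlation were the following. Of 14 markers of NK and cytotoxic cells 12 fell (adjusted p = 0.225 with an estimated correlation), with Tbx21 at -1.06 ± 0.126 and Klrd1 at -1.22 ± 0.175. Of 14 erythroid markers 12 fell (adjusted p = 0.109 with an estimated correlation), with Slc4a1 at -1.92 ± 0.206 and Alas2 at -1.46 ± 0.203. Of 32 mitosis genes 18 fell (adjusted p = 0.684 with an estimated correlation), with Kif20a at -0.96 ± 0.217 and Cenpe at -0.92 ± 0.187. Of 20 genes of fibroblasts and extracellular matrix 9 fell and 1 rose (adjusted p = 0.654 with an estimated correlation), with Col3a1 at -1.19 ± 0.168 (-0.32 by a dimmer probe) and Pdgfrb at -0.80 ± 0.0729. DNA replication (9 of 30 fell, adjusted p = 0.886 with an estimated correlation) and cytosolic ribosomal proteins (12 of 25 fell, adjusted p = 0.76 with an estimated correlation) also passed with the preset correlation alone. So did CAR and PXR targets (6 of 20 rose, 1 fell, adjusted p = 0.369 with an estimated correlation) and circadian clock genes (7 of 18 rose, 3 fell, adjusted p = 0.202 with an estimated correlation). The remaining 22 lists did not differ from other genes by camera with the preset correlation (adjusted p 0.213 to 0.893). They included alveolar type 2 cells (1 of 19 rose, 6 fell), alveolar type 1 cells (1 of 15 rose, 4 fell), club cells (3 of 19 rose, 3 fell) and ciliated cells (0 of 24 changed). Also among them were endothelial cells (1 of 20 rose, 4 fell), muscle (3 of 19 fell), adipocytes (2 of 13 rose), macrophages (5 of 23 fell), neutrophils (2 of 19 rose) and platelets (1 of 9 fell). The same held for inflammatory cytokines and chemokines (3 of 20 rose, 8 fell), acute phase proteins (1 of 21 rose), DNA repair (7 of 32 rose, 4 fell) and oxidative phosphorylation (6 of 30 fell). It held as well for cholesterol synthesis (3 of 25 rose, 7 fell), fatty acid synthesis (3 of 20 rose, 3 fell) and fatty acid oxidation (3 of 27 rose, 5 fell). The others were gluconeogenesis (1 of 15 rose, 1 fell), bile acid genes (0 of 9 changed) and hepatocytes (0 of 16 changed). The last were male-biased liver genes (3 of 17 rose, 2 fell) and stellate, biliary and endothelial liver cells (2 of 16 rose, 6 fell). With fry, macrophages, alveolar type 2 cells, oxidative phosphorylation and stellate, biliary and endothelial liver cells did pass, while DNA replication did not. Alveolar type 2 cells also passed by camera in the Cy5 channel alone.

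**Figure D1:**
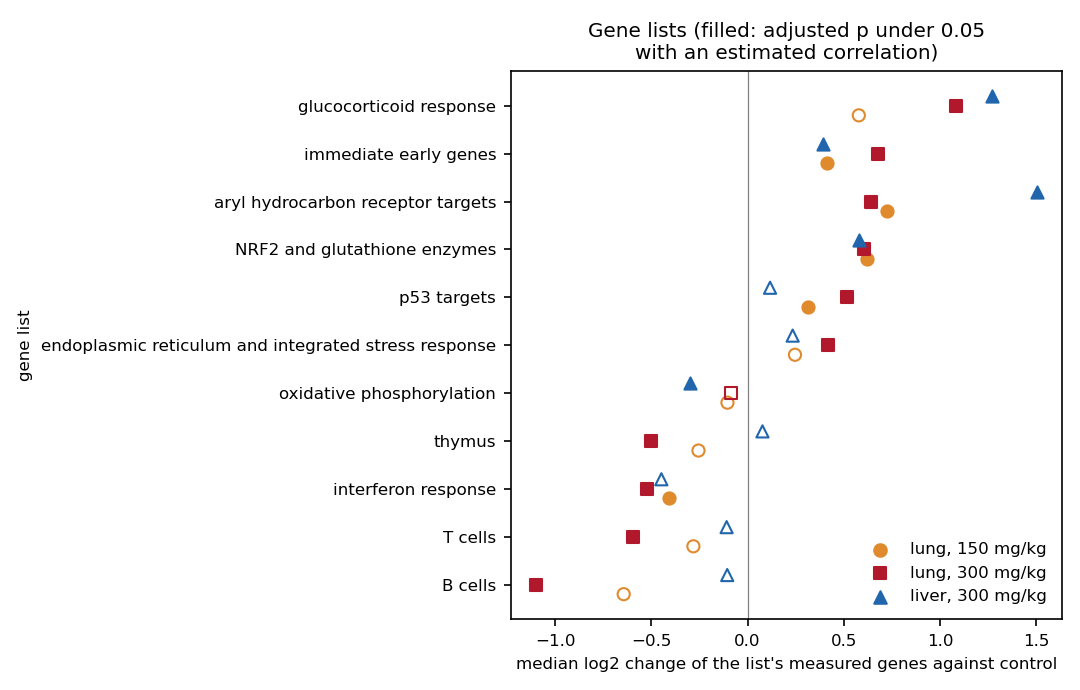
Median log2 change against control (horizontal axis) of the measured genes of 11 fixed lists (vertical axis) in lung at 150 mg/kg (circles), lung at 300 mg/kg (squares) and liver at 300 mg/kg (triangles), filled where the adjusted p with an estimated correlation was under 0.05. B cell markers lie at -1.10 in lung at 300 mg/kg and glucocorticoid response genes at 1.09, while the liver value of oxidative phosphorylation, -0.30, turned to 0.06 with median centring.

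The lung arrays came from 6 slides scanned on 2 days, and each group also kept to certain positions on the slides. Within scan 1 and within scan 2, 6367 and 6364 of the 6368 genes changed in the same direction, which is partly built in because the same arrays called these genes. The count was 7330 with scan day and 7507 with the replicate number of the titles as a block. With position on the slide as a block the count fell to 2790 and the median standard error grew from 0.065 to 0.116, and Cyp26b1 (-1.98), Cenpe (-0.79) and Kif20a (-0.81) no longer passed. With the scanner's own log ratio Cyp1a1 changed by 2.56, and Fcmr (-0.16), Klrd1 (-1.67) and Alas2 (-0.39) did not pass.

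At 150 mg/kg the question was which of these changes appeared at the lower dose. Cyp1b1 rose 25.7-fold, Cyp1a1 25.4-fold, Nqo1 21.4-fold and Ahrr 21.1-fold (n = 7 against 8 controls). Cdkn1a rose 4.49-fold and the iron exporter Slc40a1 rose by 2.66 ± 0.104 on the log2 scale. Interferon response genes fell at this dose too, and Esm1 fell by 2.18.

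In lung at 150 mg/kg 4637 of 19453 genes changed (1840 up, 2797 down), 472 of them at least 1.5-fold (208 up, 264 down) and 103 at least 2-fold (52 up, 51 down). The log2 change was 4.68 ± 0.110 for Cyp1b1 (adjusted p 7.09e-19), 4.67 ± 0.167 for Cyp1a1 (1.53e-15), 4.42 ± 0.121 for Nqo1 (1.12e-17), 4.40 ± 0.129 for Ahrr (3.53e-17) and 2.17 ± 0.111 for Cdkn1a (1.68e-12). Further large rises were those of Hspa1a (3.27 ± 0.406), Srxn1 (3.16 ± 0.128) and Maff (2.42 ± 0.0882). Large falls were those of Cyp26b1 (-2.25 ± 0.406, groups overlapping), Esm1 (-2.18 ± 0.168), Prdm8 (-1.90 ± 0.119), Tnfsf10 (-1.60 ± 0.0775), Rsad2 (-1.59 ± 0.107), Slc4a1 (-1.56 ± 0.206) and Armcx4 (-1.41 ± 0.123). All 7 treated arrays lay beyond the control mean for each of these genes. Dimmer probes of Cyp1b1 (0.52), Prdm8 (-0.27) and Rsad2 (-0.44 to -0.28) changed less.

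Of the 17 lists that passed at 150 mg/kg, 5 did so with an estimated correlation as well. NRF2 and glutathione enzymes rose in 22 of 34 members (6.08e-22 and 3.88e-05; 24 when adjusted over the list alone), with Gstp1 at 2.10 ± 0.0742 and Txnrd1 at 1.74 ± 0.0673. Aryl hydrocarbon receptor targets rose in 9 of 15 (2.31e-14 and 3.88e-05; 9 when adjusted over the list alone). Of 36 p53 targets 21 rose and 2 fell (7.35e-11 and 0.0188; 27 when adjusted over the list alone), with Gdf15 at 1.54 ± 0.157, Plk3 at 1.07 ± 0.0898, Mdm2 at 0.32 ± 0.0763 (adjusted p 0.00287) and Ccng1 at 0.30 ± 0.0911 (adjusted p 0.018). Of 20 immediate early genes 13 rose (7.62e-09 and 0.049; 15 when adjusted over the list alone), with Klf4 at 1.27 ± 0.152 and Ier3 at 0.90 ± 0.081. Of 23 interferon response genes 20 fell (8.45e-12 and 0.0188; 20 when adjusted over the list alone). B cell markers fell in 19 of 25 (adjusted p = 0.0583 with an estimated correlation), and T cell markers in 13 of 24 (adjusted p = 0.218 with an estimated correlation), with Cd3d at -0.51 ± 0.0944. Glucocorticoid response genes rose in 9 of 16 (adjusted p = 0.164 with an estimated correlation), with Klf9 at 1.09 ± 0.102 and Tsc22d3 at 1.34 ± 0.207. The call was also lost for erythroid cells (9 of 14 fell, adjusted p = 0.109 with an estimated correlation), thymus (5 of 8 fell, adjusted p = 0.123 with an estimated correlation) and the endoplasmic reticulum and integrated stress response (7 of 20 rose, adjusted p = 0.164 with an estimated correlation). It was lost for mitosis (9 of 32 fell, adjusted p = 0.786 with an estimated correlation) and endothelial cells (1 of 20 rose, 6 fell, adjusted p = 0.644 with an estimated correlation). With adjusted p = 0.492 with an estimated correlation for each, it was lost for oxidative phosphorylation (8 of 30 fell), CAR and PXR targets (3 of 20 rose, 1 fell), alveolar type 1 cells (7 of 15 fell) and alveolar type 2 cells (1 of 19 rose, 4 fell). The other 23 lists had adjusted p from 0.0738 to 0.921. Members changed in DNA repair (5 of 32 rose, 2 fell), DNA replication (3 of 30 fell), NK and cytotoxic cells (2 of 14 fell) and macrophages (5 of 23 fell). They changed in neutrophils (1 of 19 rose), club cells (1 of 19 rose, 3 fell) and fibroblasts (2 of 20 rose, 6 fell). The same was so for muscle (1 of 19 fell), adipocytes (1 of 13 rose), circadian clock (5 of 18 rose, 4 fell) and cytosolic ribosomal proteins (1 of 25 rose, 2 fell). They also changed in inflammatory genes (1 of 20 rose, 2 fell), cholesterol synthesis (3 of 25 rose, 6 fell), fatty acid oxidation (3 of 27 rose, 2 fell), fatty acid synthesis (2 of 20 rose, 2 fell), male-biased liver genes (2 of 17 rose, 2 fell), stellate, biliary and endothelial liver cells (1 of 16 rose, 2 fell) and acute phase proteins (1 of 21 fell). None changed in platelets, ciliated cells, hepatocytes, bile acid genes or gluconeogenesis.

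Within scan 1 and scan 2 the median change of each of the 5 lists kept its sign, from 0.69 to 0.94 for aryl hydrocarbon receptor targets and from 0.32 to 0.37 for p53 targets. With the replicate number of the titles as a block 5994 genes changed, with scan day as a block 5824, and with position on the slide as a block 374, where the median standard error grew from 0.065 to 0.161 and Mdm2, Ccng1, Klf4, Tsc22d3, Hspa1a, Cyp26b1 and Slc4a1 no longer passed. With the scanner's own log ratio Cyp1a1 changed by 2.08. The call of Cd3d was lost with normexp fitted on all spots. That of Ccng1 was lost without the arrays whose normexp fit had been disturbed. By list with the preset correlation, DNA replication passed with the replicate number or the slide as a block. The slide block also made hepatocytes and ribosomal proteins pass and ended the call of alveolar type 2 cells.

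Both doses were compared with the same controls, so the overlap was tested against simulated groups without a response that shared them. Of the genes that changed at both doses, 3801 of 3803 did so in the same direction (1446 up, 2355 down), where 229 and 568 were expected if the calls were independent. None of 100 simulations gave a shared call. The covariance of the log2 changes was 0.0619, against a simulated median of 0.00390 and a highest simulated value of 0.0144. When the 8 controls were split 4 and 4 so that each dose had its own, a median of 2445 genes (range 2258 to 2607) changed in the same direction at both doses. The correlation of the log2 changes across genes was 0.889 with shared controls and a median of 0.808 with split controls, where genes are not independent replicates. Simulated groups without a response that shared the controls gave a median correlation of 0.490 and a highest of 0.821, so part of the 0.889 may come from the shared controls.

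**Figure D2:**
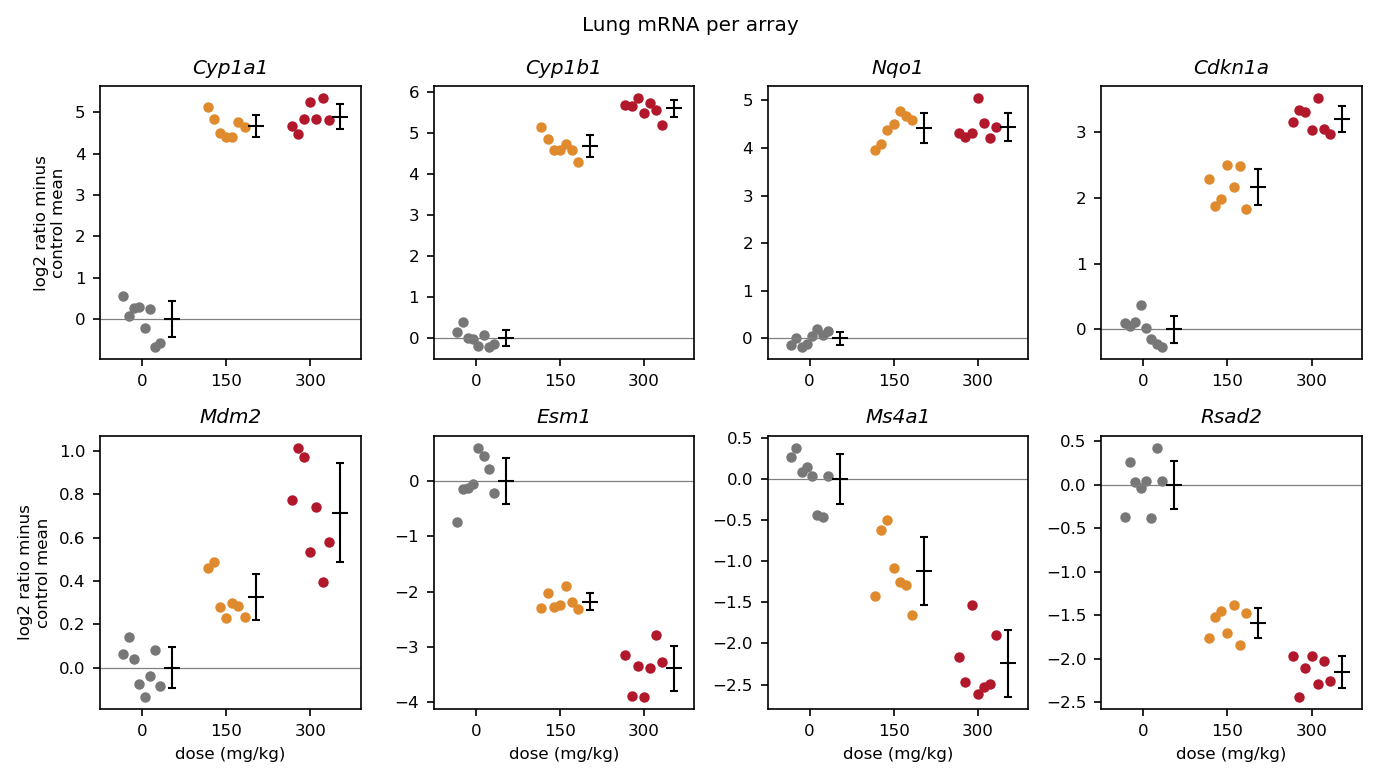
Log2 ratio to the reference minus the control mean (vertical axis) for 8 genes in each lung mRNA array at 0, 150 and 300 mg/kg (horizontal axis), where each point is an array and the bars are the group mean and SD. Cdkn1a lies between 1.84 and 2.51 at 150 mg/kg and between 2.97 and 3.52 at 300 mg/kg.

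The direct comparison of 300 with 150 mg/kg asked which lung genes differed between doses. The p53 target Cdkn1a was 2.05-fold higher at 300 than at 150 mg/kg (1.03 ± 0.115, adjusted p 1.43e-05, n = 7 each), and Cyp1b1 was 1.88-fold higher (0.91 ± 0.114, adjusted p 5.38e-05). For Cyp1a1 (0.22 ± 0.172, adjusted p 0.573) and Nqo1 (0.02 ± 0.125, adjusted p 0.961) the difference did not pass. The mean log ratio of Cyp1a1 was 7.65 at 300 and 7.44 at 150 mg/kg, and ratios of such bright spots may be too small. Lymphocyte markers were lower at the higher dose, and glucocorticoid response genes were higher.

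Of 19453 genes 1023 differed between the doses (380 higher at 300 mg/kg, 643 lower), 100 of them at least 1.5-fold (51 higher, 49 lower). The glutathione-degrading enzyme Chac1 was higher by 1.66 ± 0.281 (adjusted p 0.000836, in 6 of 7 arrays), Bean1 by 1.44 ± 0.102 (1.68e-08), the cystine transporter Slc7a11 by 1.21 ± 0.174 (0.000222), Ramp3 by 1.12 ± 0.143 (6.9e-05) and Tiparp by 1.08 ± 0.230 (0.00572). Esm1 was lower (-1.21 ± 0.174, adjusted p 0.000203), as were Ms4a1 (-1.12 ± 0.185), Rgs3 (-1.005 ± 0.110), Cd79b (-0.90 ± 0.146) and Cd8b1 (-0.90 ± 0.139, where a dimmer probe gave 0.12). Mdm2 was higher by 0.39 ± 0.0788 (adjusted p 0.0038) and Ccng1 by 0.40 ± 0.0941 (adjusted p 0.013). Dimmer probes gave -0.45 to 0.0754 for Rgs3, 0.43 to 0.50 for Slc7a11 and 0.17 for Mdm2.

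Of the 16 lists that passed between the doses, 7 did so with an estimated correlation as well. T cell markers were lower in 11 of 24 (5.54e-16 and 0.015; 19 when adjusted over the list alone) and B cell markers in 14 of 25 (7.55e-16 and 0.038; 17 when adjusted over the list alone). So were thymus markers in 3 of 8 (4.08e-05 and 0.038; 5 when adjusted over the list alone) and interferon response genes in 6 of 23 (5.14e-09 and 0.038; 10 when adjusted over the list alone). The p53 targets were higher in 11 of 36 (2.37e-13 and 0.015; 18 when adjusted over the list alone), glucocorticoid response genes in 5 of 16 (7.71e-12 and 0.038; 12 when adjusted over the list alone) and genes of the endoplasmic reticulum and integrated stress response in 7 of 20 (4.5e-08 and 0.0486; 11 when adjusted over the list alone). The call was lost for NK and cytotoxic cells (8 of 14 lower, adjusted p = 0.0876 with an estimated correlation) and immediate early genes (4 of 20 higher, adjusted p = 0.0876 with an estimated correlation). It was lost for NRF2 and glutathione enzymes (2 of 34 higher, 1 lower, adjusted p = 0.134 with an estimated correlation) and the circadian clock (2 of 18 higher, adjusted p = 0.102 with an estimated correlation). It was lost for endothelial cells (2 of 20 higher, adjusted p = 0.403 with an estimated correlation), alveolar type 1 cells (1 of 15 higher, adjusted p = 0.403 with an estimated correlation) and club cells (2 of 19 higher, adjusted p = 0.689 with an estimated correlation), and the medians of these 3 lists were below 0 in the Cy5 channel alone. It was lost for ribosomal proteins (2 of 25 lower, adjusted p = 0.727 with an estimated correlation) and mitosis (0 of 32 changed, adjusted p = 0.895 with an estimated correlation). The other 24 lists had adjusted p from 0.057 to 0.95. Among aryl hydrocarbon receptor targets 2 of 15 were higher, and members also differed in DNA repair (2 of 32 lower), macrophages (1 of 23 lower), erythroid cells (1 of 14 lower), alveolar type 2 cells (3 of 19 lower), fibroblasts (2 of 20 lower) and CAR and PXR targets (1 of 20 higher). The same was so for stellate, biliary and endothelial liver cells (1 of 16 higher, 1 lower), inflammatory genes (2 of 20 higher, 2 lower), fatty acid oxidation (1 of 27 higher, 1 lower), male-biased liver genes (1 of 17 higher) and gluconeogenesis (1 of 15 higher). None differed in DNA replication, neutrophils, platelets, ciliated cells, muscle, adipocytes, hepatocytes, cholesterol synthesis, fatty acid synthesis, bile acid genes, acute phase proteins or oxidative phosphorylation.

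Within the scans 971 genes (scan 1) and 124 genes (scan 2) passed, and the count was 1895 with scan day, 1547 with the replicate number and 40 with position on the slide as a block. With the position block Chac1, Slc7a11, Tiparp, Esm1, Ms4a1, Rgs3, Cd79b, Cd8b1, Mdm2 and Ccng1 no longer passed, while Mdm2 and Ccng1 were also lost with median centring (0.38 and 0.39) or Cy5 alone (0.25 and 0.28). Cd8b1 was also lost with the scanner's own log ratio, Tiparp with only titles 1 to 6 and Ccng1 with only the groups compared.

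In liver the question was which genes changed at 300 mg/kg. No control array stood above background for Cyp1a1, which rose 97.0-fold as a ratio to the reference and at least 106-fold in normalized Cy5 signal. The conjugating enzymes Gsta1 and Gsta2 rose 11.9-fold and 8.87-fold, and Nqo1 rose 9.5-fold. The lipid synthesis gene Fasn fell by 2.11 on the log2 scale. Genes of oxidative phosphorylation fell with loess (median -0.30) but not with median centring (0.06).

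Of 15308 liver genes 2624 changed (903 up, 1721 down), 845 at least 1.5-fold (386 up, 459 down) and 277 at least 2-fold (157 up, 120 down). The log2 change was 4.25 ± 0.207 for Cbr3 (adjusted p 1.51e-07), 3.57 ± 0.166 for Gsta1 (1.05e-07), 3.29 ± 0.237 for Gadd45g (3.76e-06), 3.25 ± 0.0897 for Nqo1 (1.44e-09), 3.22 ± 0.0916 for Hspa2 (1.44e-09) and 3.15 ± 0.130 for Gsta2 (4.9e-08). The largest falls were those of Hsd3b4 (-2.78 ± 0.355), the cell cycle regulator E2f8 (-2.78 ± 0.284), Slc25a30 (-2.63 ± 0.236), the clock genes Nr1d1 (-2.25 ± 0.183) and Dbp (-2.23 ± 0.186), Serpina4-ps1 (-2.23 ± 0.363), Fasn (-2.11 ± 0.177) and Tsc22d1 (-2.11 ± 0.111). No control array stood above background for Cyp1b1 and Ahrr either. As ratios they rose 5.71-fold (adjusted p 6.28e-05) and 2.84-fold (adjusted p 3.7e-06), and in normalized Cy5 signal at least 6.01-fold and 2.60-fold. Cyp1a2, another listed target of the aryl hydrocarbon receptor, changed by -0.22 ± 0.139 (adjusted p 0.332) as a ratio to the reference but by 3.66 in the Cy5 channel alone, and its reference channel moved with the sample. The p53 targets Cdkn1a (2.54 ± 0.226, adjusted p 2.04e-05), Mdm2 (0.95 ± 0.0951, 4.14e-05) and Ccng1 (0.98 ± 0.180, 0.00291) rose. Dimmer probes gave -0.62 to -0.0494 for Nr1d1, -1.15 for E2f8, 0.39 for Ccng1 and 0.45 for Cyp1a2. All 5 treated arrays lay beyond the control mean for each named gene that passed.

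Of the 15 lists that passed in liver, 5 did so with an estimated correlation as well. NRF2 and glutathione enzymes rose in 20 of 33 and fell in 1 (9.32e-17 and 0.0393; 22 when adjusted over the list alone), with Srxn1 at 2.83 ± 0.118. Glucocorticoid response genes rose in 12 of 16 (3.2e-15 and 0.0393; 15 when adjusted over the list alone), with the metallothionein Mt2 at 3.06 ± 0.255, Cebpd at 1.96 ± 0.134 and Tsc22d3 at 1.48 ± 0.104. Aryl hydrocarbon receptor targets rose in 8 of 11 (3.92e-14 and 0.0393; 8 when adjusted over the list alone). Immediate early genes rose in 7 of 18 and fell in 2 (0.000235 and 0.0478; 11 when adjusted over the list alone), with Myc at 2.00 ± 0.170 (0.81 to 1.76 by dimmer probes) and Klf4 at 1.64 ± 0.127. Oxidative phosphorylation genes fell in 20 of 30 (6.06e-09 and 0.0478; 25 when adjusted over the list alone), with Ndufa1 at -0.45 ± 0.0615 and Cox6c at -0.44 ± 0.066. Their median of -0.30 turned to 0.06 with median centring in place of loess, with 0 of the 30 genes called, so the fall depends on how the arrays were scaled.

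The call was lost in liver for CAR and PXR targets (11 of 22 rose, adjusted p = 0.222 with an estimated correlation), among them Cyp2b10 (2.98 ± 0.175), Cyp2b13 (3.15 ± 0.190, where a dimmer probe gave 0.11) and the P450 reductase Por (1.94 ± 0.158). It was lost for fatty acid synthesis (12 of 19 fell, adjusted p = 0.107 with an estimated correlation), with Srebf1 at -1.51 ± 0.137 and Elovl6 at -1.53 ± 0.160, and for the interferon response (15 of 20 fell, 1 rose, adjusted p = 0.222 with an estimated correlation), with Rtp4 at -1.07 ± 0.0993 and Ifit3 at -0.90 ± 0.0872. The p53 targets (9 of 32 rose, 2 fell, adjusted p = 0.316 with an estimated correlation) included Trp53inp1 at 1.47 ± 0.173. Male-biased liver genes (6 of 19 fell, adjusted p = 0.222 with an estimated correlation) included Hsd3b5 at -1.78 ± 0.184 and Socs2 at -1.47 ± 0.221, and macrophages (6 of 20 fell, 1 rose, adjusted p = 0.583 with an estimated correlation) included Lyz2 at -1.28 ± 0.131 (-0.47 by a dimmer probe). The call was lost for fatty acid oxidation (2 of 27 rose, 7 fell, adjusted p = 0.583 with an estimated correlation), fibroblasts (3 of 18 fell, adjusted p = 0.397 with an estimated correlation) and DNA replication (1 of 28 rose, 8 fell, adjusted p = 0.688 with an estimated correlation). The club cell list passed upward (2 of 15 rose, adjusted p = 0.229 with an estimated correlation) with a mean of 0.71 and a median of -0.04. The other 25 lists had adjusted p from 0.054 to 0.931. Among them were B cells (3 of 14 fell), T cells (1 of 12 fell), NK and cytotoxic cells (1 of 5 fell), thymus (0 of 6 changed), erythroid cells (2 of 9 fell), neutrophils (0 of 7 changed), platelets (0 of 6 changed), hepatocytes (1 of 19 rose, 1 fell) and stellate, biliary and endothelial liver cells (1 of 16 rose, 4 fell). Stress response genes of the endoplasmic reticulum (5 of 20 rose, 3 fell), the circadian clock (6 of 17 rose, 4 fell), cholesterol synthesis (1 of 25 rose, 9 fell) and bile acid genes (1 of 17 rose, 2 fell) did not pass as lists either. This was also so for gluconeogenesis (1 of 16 rose, 2 fell), acute phase proteins (1 of 22 rose, 2 fell), ribosomal proteins (2 of 25 fell), DNA repair (6 of 30 fell), mitosis (1 of 23 fell) and inflammatory genes (1 of 14 rose, 1 fell). Nor did alveolar type 2 (1 of 11 rose, 2 fell) and type 1 cells (1 of 10 rose, 1 fell), ciliated cells (1 of 6 fell), endothelial cells (2 of 18 rose, 3 fell), muscle (0 of 15 changed) and adipocytes (1 of 8 rose, 1 fell).

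Within the 4 liver slides that held both groups, 99.2% to 99.8% of the 2624 genes kept their direction. Each of these slides holds 1 array per group of the fit that called the genes, so this agreement is partly built in. The count was 2758 with the replicate number and 3644 with the slide as a block. Median centring gave 995 genes, 72.4% of them upward against 34.4%, and the scanner's own log ratio ended the calls of Hsd3b4 (-2.03), Serpina4-ps1 (-0.98) and Hsd3b5 (0.03).

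The difference between tissues asked whether the response to 300 mg/kg was the same in lung and liver. Esm1 fell in lung (-3.39) and not in liver (-0.04), giving a difference of -3.35 ± 0.254 (lung minus liver). The lipoprotein lipase gene Lpl rose in lung (1.11) and fell in liver (-1.96). B cell markers fell more in lung, and genes of fatty acid synthesis responded more positively in lung than in liver.

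Of 14466 genes tested in both tissues 2822 responded differently (1594 more positively in lung, 1228 more positively in liver), 1026 by at least 1.5-fold (506 and 520). Of the 2822, 1549 had log2 changes of opposite sign (204 of them past the threshold in both tissues). Of the others 621 had the larger change in lung and 652 in liver. The difference was 3.11 ± 0.174 for Ahrr (adjusted p 1.1e-12) and 3.08 ± 0.262 for Cyp1b1 (2.06e-09). No liver control array stood above background for either, so the size of both differences is uncertain, and the scanner's own log ratio gave 1.34 and 1.08. It was 3.07 ± 0.137 for Lpl (1.59e-14), 2.87 ± 0.215 for Slc25a30 (1.74e-10) and 2.85 ± 0.179 for Slc40a1 (1.02e-11). It was -3.35 for Esm1 (2.25e-10), -3.24 ± 0.137 for Hspa2 (8.88e-15), -2.87 ± 0.177 for Gsta1 (8.19e-12) and -2.80 ± 0.147 for Fmo2 (3.21e-13, where a dimmer probe gave -0.90). Cyp1a1 rose more in liver (-1.72 ± 0.258, adjusted p 2.05e-05, with no liver control above background), Nqo1 rose more in lung (1.19 ± 0.151, 1.65e-06), and the difference was 0.66 ± 0.231 for Cdkn1a (adjusted p 0.0433), which turned to -0.0720 with the scanner's own log ratio. For Mdm2 (-0.24 ± 0.129, adjusted p 0.219) and Ccng1 (0.31 ± 0.179, adjusted p 0.263) no difference passed, though that of Mdm2 did with the scanner's own log ratio (-0.53).

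Of 13 lists that passed for the tissue difference, 2 did so with an estimated correlation as well. The response of B cell markers was more negative in lung than in liver in 10 of 14 members (2.22e-10 and 0.0284, and 10 when adjusted over the list alone). That of fatty acid synthesis genes was more positive in 12 of 19 (8.16e-07 and 0.0284, and 13 when adjusted over the list alone). In this paragraph lower and higher mean a more negative and a more positive response in lung than in liver, not a level of expression. The call was lost for CAR and PXR targets (8 of 19 lower, adjusted p = 0.213 with an estimated correlation) and p53 targets (14 of 32 higher, adjusted p = 0.213 with an estimated correlation). The same was so for thymus (4 of 6 lower, adjusted p = 0.0823 with an estimated correlation), T cells (5 of 12 lower, 1 higher, adjusted p = 0.288 with an estimated correlation) and male-biased liver genes (5 of 16 higher, adjusted p = 0.259 with an estimated correlation). It was lost for fatty acid oxidation (12 of 26 higher, 2 lower, adjusted p = 0.483 with an estimated correlation). With adjusted p = 0.675 with an estimated correlation for each, it was lost for mitosis (2 of 23 lower), the interferon response (6 of 20 lower, 2 higher) and macrophages (2 of 19 higher, 1 lower). Oxidative phosphorylation (8 of 30 higher, adjusted p = 0.31 with an estimated correlation) and the endoplasmic reticulum and integrated stress response (5 of 20 higher, adjusted p = 0.656 with an estimated correlation) had medians below 0 with median centring. The other 26 lists had adjusted p from 0.0545 to 0.929, and among them NRF2 enzymes differed both ways (10 of 33 higher, 9 lower), as did aryl hydrocarbon receptor targets (3 of 10 higher, 3 lower) and glucocorticoid response genes (3 of 16 higher, 4 lower). Further members differed in immediate early genes (5 of 18 higher, 1 lower), the circadian clock (5 of 17 higher, 1 lower) and cholesterol synthesis (6 of 25 higher, 2 lower). Stellate, biliary and endothelial liver cells (4 of 16 higher), erythroid cells (1 of 8 higher, 4 lower) and adipocytes (3 of 8 higher, 1 lower) had members that differed. So did DNA repair (3 of 30 higher, 1 lower), DNA replication (1 of 28 higher, 1 lower) and inflammatory genes (2 of 13 higher, 2 lower). The same was so for endothelial cells (1 of 18 higher, 3 lower), alveolar type 2 (2 of 11 higher, 2 lower) and type 1 cells (1 of 10 higher, 2 lower), club cells (2 of 14 lower), ciliated cells (1 of 6 lower), hepatocytes (1 of 13 higher, 1 lower), gluconeogenesis (2 of 14 higher), bile acid genes (1 of 9 lower) and acute phase proteins (1 of 19 lower). None differed in neutrophils, platelets, fibroblasts, muscle or ribosomal proteins. All 4 NK markers measured were lower, too few for the list test.

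Among the 14745 genes measured in both single-tissue fits, 406 rose and 747 fell in both tissues, where 127 and 351 were expected if the calls were independent, and 206 changed in opposite directions. With median centring 1298 genes differed between tissues, 28.4% of them more positively in lung, and Cdkn1a was lost (0.35). Cdkn1a was also lost when 1 array was left out, for lung control arrays 2, 5, 6, 7 and 8 (0.63 to 0.67), lung arrays 1, 2, 3 and 6 at 300 mg/kg (0.61 to 0.67), liver control arrays 1, 3, 5 and 6 (0.61 to 0.69) and liver array 1 at 300 mg/kg (0.42).

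**Figure D3:**
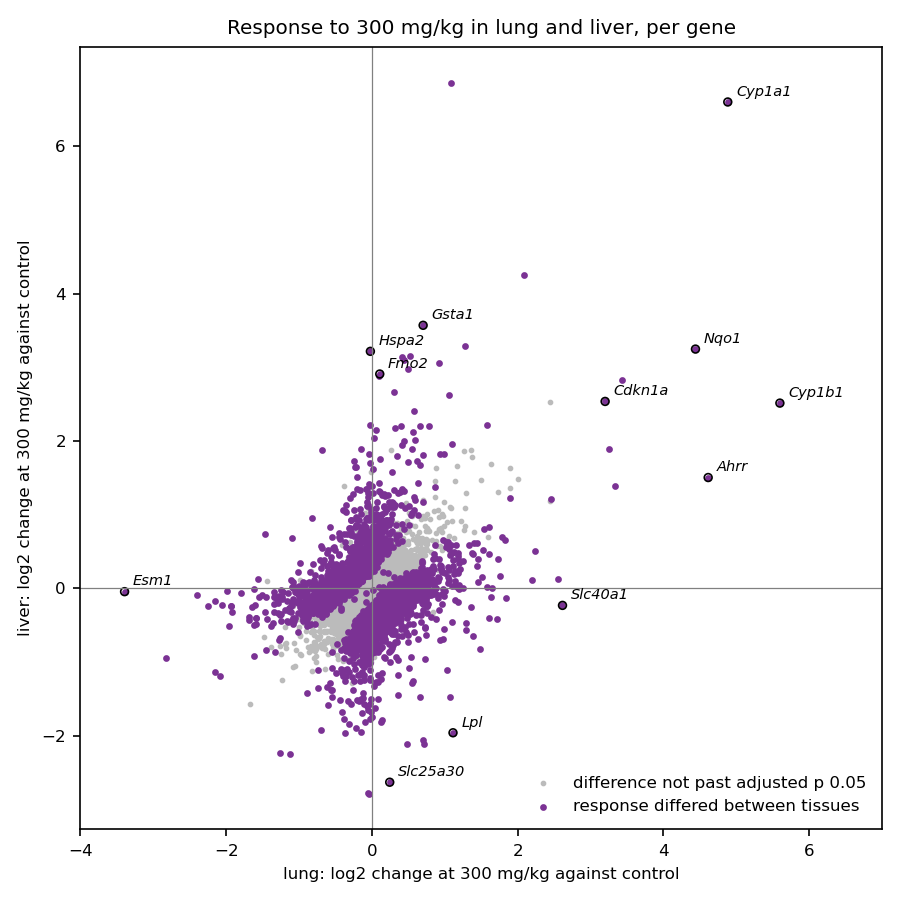
Log2 change at 300 mg/kg against control in lung (horizontal axis) and liver (vertical axis), where each point is a gene, purple where the response differed between tissues and grey where the difference did not pass. Esm1 lies at -3.39 in lung and -0.04 in liver.

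In lung microRNA the question was which microRNAs changed at either dose. At 300 mg/kg, miR-34a and miR-34c, which p53 induces, rose by 0.59 ± 0.0952 and 0.77 ± 0.197 (n = 5 against 3 controls), and 4 members of the miR-29 family rose. Of 10 lymphoid and leukocyte microRNAs 3 fell, miR-142-5p by 1.38, miR-142-3p by 1.31 and miR-150 by 1.31 on the log2 scale, though as a list they did not pass (adjusted p 0.212). Against control array 6 alone, the control that was not dim, these 3 changes were -0.76, -0.71 and -0.61. The rises were then 0.45 for miR-34a, 0.65 for miR-34c, 0.17 for miR-29a, 0.31 for miR-29b, 0.30 for miR-29c and 0.18 for miR-29c*. The liver microRNA miR-122 fell at both doses.

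Of 274 microRNAs tested 18 changed at 300 mg/kg (12 up, 6 down), with a median absolute log2 change of 0.47. The adjusted p was 0.00661 for miR-34a, 0.0456 for miR-34c, 0.0334 for miR-29c (0.66 ± 0.147), 0.0162 for miR-29b (0.46 ± 0.0917), 0.0412 for miR-29a (0.48 ± 0.118) and 0.0412 for the epithelial miR-200c (0.47 ± 0.115). It was 0.00661 for miR-142-5p (-1.38 ± 0.222), 0.012 for miR-150 (-1.31 ± 0.240) and 0.0129 for miR-142-3p (-1.31 ± 0.248). The controls of these 3 varied more (SD 0.64, 0.69 and 0.71, n = 3) than the arrays at 300 mg/kg (SD 0.20, 0.12 and 0.21, n = 5). Their standard errors come from a spread shared by all groups, so they may understate the uncertainty of the control mean. MiR-122 (-1.64 ± 0.286, adjusted p 0.00976), miR-503 (-0.36 ± 0.0464, 0.00307) and miR-127 (-0.16 ± 0.0419, 0.0478) are lower bounds on the fall, since 3, 1 and 5 of the 5 treated arrays lay at the lowest value used. Of the other miR-34 forms, miR-34b-5p gave 0.89 ± 0.272 (adjusted p 0.0783), miR-34b-3p -0.25 ± 0.205 (0.322) and miR-34c* 0.04 ± 0.051 (0.593, with 1 control array at the lowest value used). All 5 treated arrays lay beyond the control mean for each microRNA that passed.

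By list, 4 of 5 miR-29 members rose (adjusted p 0.000196, with 4 when adjusted over the list alone; adjusted p = 0.134 with an estimated correlation), and 2 of 7 members of the miR-200 family rose (6.29e-05, with 6 when adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). Of the 5 miR-34 forms 2 rose (0.0103, with 3 when adjusted over the list alone; adjusted p = 0.134 with an estimated correlation). The medians of these 3 families stayed above 0 in each of the 5 other scalings and with a lower floor, from 0.29 to 0.81 for miR-29, from 0.34 to 0.72 for miR-200 and from 0.44 to 0.94 for miR-34, while the median of all microRNAs moved from -0.06 to -0.41 with normexp. All 12 members of the miR-17-92 list had negative changes and none passed (list 0.0224; adjusted p = 0.555 with an estimated correlation), though 2 were positive with the 75th percentile over all probes and with the series values, and 1 with quantile scaling. The let-7 family (0 of 14 changed, 0.0224; adjusted p = 0.399 with an estimated correlation) and stress microRNAs (0 of 10 changed, 0.0256; adjusted p = 0.399 with an estimated correlation) had passed with the preset correlation alone. None of 5 muscle (0.733) or 10 stromal (0.141) microRNAs changed. Too few for the list test, 3 erythroid microRNAs had a median of -1.06 and none passed, and 1 of 4 liver microRNAs fell.

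At 150 mg/kg 1 of 274 microRNAs changed. This was miR-122 (-1.86 ± 0.286, adjusted p 0.0134), again with 3 of 5 treated arrays at the lowest value used. The next smallest p belonged to miR-34a (0.42 ± 0.0952), miR-151-5p (0.44 ± 0.109), miR-150 (-0.91 ± 0.240) and miR-127 (-0.16 ± 0.0419, a lower bound on the fall with 4 of 5 treated arrays at the lowest value used), each with adjusted p 0.103. Among the other miR-34 forms, miR-34c gave 0.53 ± 0.197 (0.103), miR-34b-5p 0.62 ± 0.272 (0.123), miR-34b-3p -0.33 ± 0.205 (0.219) and miR-34c* -0.03 ± 0.051 (0.595). The miR-200 family (0.00036), miR-29 family (0.00821) and let-7 family (0.0492) passed as lists with the preset correlation, with adjusted p = 0.342, 0.342 and 0.552 with an estimated correlation, and the other 6 lists tested had adjusted p from 0.067 to 0.772. Between 300 and 150 mg/kg 0 of 274 microRNAs differed by limma (7 at an unadjusted p under 0.05). The smallest adjusted p was that of miR-503 (-0.21 ± 0.0402, 0.0786, with 1 array at 300 mg/kg at the lowest value used), followed by miR-142-5p (-0.63 ± 0.192), miR-29b (0.20 ± 0.0794), miR-142-3p (-0.52 ± 0.215) and miR-224 (0.03 ± 0.0143, with 1 array at 150 mg/kg at the lowest value used), each with adjusted p 1. The miR-34 forms gave 0.17 ± 0.0824 (miR-34a), 0.24 ± 0.171 (miR-34c), 0.27 ± 0.235 (miR-34b-5p), 0.08 ± 0.177 (miR-34b-3p) and 0.07 ± 0.0442 (miR-34c*), also with adjusted p 1. As lists, the miR-29 family (3.57e-06; adjusted p = 0.0504 with an estimated correlation), lymphoid microRNAs (9.82e-06; adjusted p = 0.0781 with an estimated correlation) and the miR-34 family (0.000386; adjusted p = 0.0504 with an estimated correlation) passed with the preset correlation alone. So did stress microRNAs (0.00978; adjusted p = 0.336 with an estimated correlation), the miR-200 family (0.0147; adjusted p = 0.381 with an estimated correlation) and the miR-17-92 list (0.0498; adjusted p = 0.66 with an estimated correlation). Let-7 (0.35), muscle (0.582) and stromal microRNAs (0.391) did not.

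The microRNA counts rest on 3 control arrays. At 300 mg/kg the 18 became 157 without control array 6, 48 without control array 3 and 10 without control array 1, and 9, 7, 7, 11 and 7 without treated arrays 1, 2, 3, 5 and 6. At 150 mg/kg the 1 became 150, 17 and 2 without control arrays 6, 3 and 1. Between the doses 0 became 1 without treated array 5. With the replicate number of the titles as a block 1 microRNA passed at 300 mg/kg and with the slide as a block 39 did, while all 18 kept their direction within each of the 2 slides. The other scalings gave 8 to 219 at 300 mg/kg, and those that ended the calls of most of the microRNAs named above were the replicate block and the scanner's own total gene signal. With 1 array left out miR-34c was lost without control array 1 (0.55) and without each array at 300 mg/kg (0.70 to 0.84), miR-200c without each array at 300 mg/kg (0.45 to 0.49) and miR-29b without control array 1 (0.38). MiR-29a was lost without control array 1 (0.39) or 3 (0.41) and without arrays 1, 2, 3 or 6 at 300 mg/kg (0.44 to 0.48), miR-29c without those 4 arrays (0.64 to 0.66), and miR-127 without control array 1 (-0.12) or any array at 300 mg/kg (-0.16). MiR-34b-5p at 300 mg/kg passed with normexp (0.78), the 75th percentile over all probes (1.25), the series values (0.88) and the slide block (0.87). It also passed without control array 3 (1.06) or 6 (1.07), and miR-34b-3p without control array 6 (-0.56). Without both dim controls miR-150 was -0.61 and did not pass, nor did miR-34c (0.65), miR-29a (0.17), miR-29b (0.31) and miR-29c (0.30). The call of miR-122 at 150 mg/kg was lost with the total gene signal (-2.81) and the lower floor (-2.75).

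**Figure D4:**
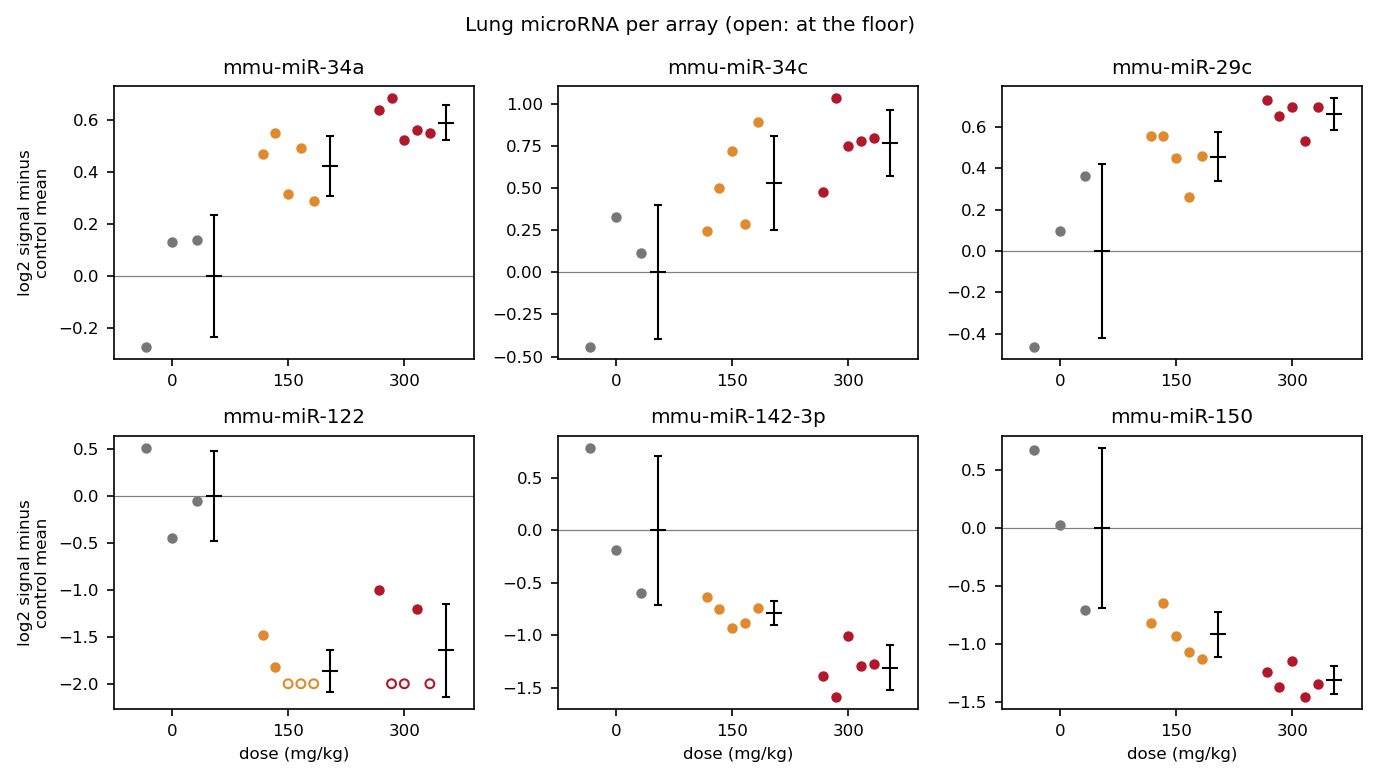
Log2 signal minus the control mean (vertical axis) for 6 microRNAs in each lung microRNA array at 0, 150 and 300 mg/kg (horizontal axis), where each point is an array, open points are at the lowest value used, and the bars are the group mean and SD. MiR-34a lies between 0.52 and 0.68 at 300 mg/kg and between -0.27 and 0.14 in controls.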

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

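The tests of the reference channel, of scan days, of the fit without dim microRNA controls and of the slide block were chosen only after the result was seen, and the other tests before. Values below that stand apart are the gap to the nearest array of the same group divided by the range of the group, and genes are given on the log2 scale.

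In lung, array 7 at 300 mg/kg stood apart as the lowest for Srxn1 (0.727 of the range) and Hspa1a (0.729, at 1.62 where the next array had 4.46) and as the highest for Cd27 (0.616) and Ramp3 (0.586). Control array 7 stood apart as the highest for Hspa1a (0.656). Single arrays also stood apart for Nqo1 at 300 mg/kg (array 5 highest, 0.618), Prdm8 at 300 mg/kg (array 8 lowest, 0.741), and at 150 mg/kg for Prdm8 (array 3 highest, 0.6246), Gstp1 (array 2 highest, 0.586) and Gdf15 (array 4 highest, 0.606). In lung microRNA at 150 mg/kg array 2 was the highest for miR-34b-3p (0.865) and miR-503 (0.730). The number of probes above background was 34009 on lung array 1 at 300 mg/kg, where the next array had 28699 (0.692), and the 75th percentile of microRNA array 5 at 300 mg/kg was 360 where the next had 303 (0.731).

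In liver, array 1 at 300 mg/kg was the lowest for Gsta1 (0.789), Cdkn1a (0.743) and Srxn1 (0.730). Array 3 was the highest for E2f8 (0.789) and array 2 for Por (0.888). Among the controls, array 6 was the highest for Srxn1 (0.889), array 5 for Cyp2b13 (0.893) and array 2 for Cox6c (0.740), and array 2 was the lowest for Myc (0.728). Chance marks about 1 in 20 groups, or 5%, and 23 of 249 groups (9.24%) had such an array. The pattern of liver array 1 was not tested further.

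The response to 300 mg/kg differed between lung and liver in 2822 genes by a test of the difference itself. It was more positive in lung for Ahrr (3.11), Cyp1b1 (3.08), Lpl (3.07), Slc25a30 (2.87), Slc40a1 (2.85), Nqo1 (1.19) and Cdkn1a (0.66), and more positive in liver for Esm1 (-3.35), Hspa2 (-3.24), Gsta1 (-2.87), Fmo2 (-2.80) and Cyp1a1 (-1.72). The tissues were scanned with different software versions and different signal measures, and with lung median signals the difference of Cdkn1a was 0.63 and no longer passed. Of 100 splits of the arrays only the real one gave as many genes, the highest other giving 1418. By the limit set beforehand chance was excluded for the count (1 of 100 splits).

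Liver Cyp1a2 changed by -0.22 as a ratio while its Cy5 signal rose by 3.33 and its Cy3 signal by 3.56. A candidate explanation is that sample signal was read in the reference channel at spots where the sample is far brighter than the reference. Of the liver probes whose Cy5 signal moved, Cy3 followed in 53.3% of the 90 with a log ratio of 4 or more and in 2.29% of the other 349, 51.0 percentage points apart, and in lung at 300 mg/kg in 45.5% of 44 against 3.62% of 387. A difference in the overall brightness of the reference was argued against by the Cy3 signals before loess and scaling between arrays. Their median change over all liver probes was -0.0327, and that of Cyp1a2 was 3.16. Ratios of other very bright transcripts may be too small in the same way, as for Hba-a1 in lung at 300 mg/kg (-0.37 as a ratio, -2.58 in Cy5), Alas2 (-1.46 and -3.04) and liver Igfbp1 (1.15 and 3.33), genes chosen after their values were seen apart from Alas2.

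The B cell, T cell and thymus lists fell together in lung at 300 mg/kg, over 53 distinct members, since the thymus list shares genes with the T cell list. A difference between scan days was argued against, since both groups were scanned on both days and the median was -0.66 in the day with the smaller change (-0.72 in the other). Position on the slide, to which each group partly kept, was not tried as a block for the lists, so it was not tested for this fall as a whole. Lymphoid tissue taken along with only some control lungs was argued against as well, since the difference between group means was 3.19 times the range of the controls and the highest array at 300 mg/kg (-0.06) lay below the lowest control (0.35). A higher glucocorticoid response in the same lungs remains open. Over 14 treated arrays, as deviations from group means, r was -0.46 (permutation p 0.0927, adjusted 0.0927) and Spearman's rho -0.51 (permutation p 0.0661, adjusted 0.0927), with r -0.79 without the 2 farthest arrays, but r was 0.80 within scan 1 and -0.70 within scan 2 (n = 7 each), so the relation does not hold within both scan days.

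The 18 microRNAs called at 300 mg/kg were compared with 3 control arrays, 2 of them dim, and 79 of 274 microRNAs differed by more than 0.5 between the dim arrays and control array 6. A fit without the dim arrays left 1 control, with the spread taken from the other groups, so whether a microRNA passed in it does not decide dimness. All 5 arrays at 300 mg/kg lay at the floor for miR-127 and 3 of 5 for miR-122, which limits their spread. In size, the changes of miR-34c (0.77 and then 0.65), miR-30c-2*, miR-23a and miR-29c* kept 0.80 to 1.12. Those of miR-150 (1.31 and then 0.61 downward), miR-29a, miR-29b, miR-29c and miR-151-5p kept 0.36 to 0.67. MiR-142-5p and miR-142-3p kept 0.55 and 0.54. The remaining ones kept 0.74 (miR-200c) to 0.97 (miR-122), apart from miR-127 (1.41). These names were chosen after their values were seen. With 1 control left dimness is not decided for the 18. All 18 of 18 kept their direction against control array 6 alone, but that array is part of the control mean behind the calls, so the agreement is partly built in. The median size was 0.31 against 0.47 with all 3 controls. A difference between slides was argued against by the fit with the slide as a block, which still called all 18. All 18 also kept their direction within each slide, but slide 2 holds control array 6 alone, so this agreement is partly built in as well.

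The arrays were also split at random into groups of the same sizes. For the gene counts only the real split among those drawn reached the real value, so chance was excluded for the counts by the limit set beforehand. In lung at 300 mg/kg 1 of 100 splits reached 6368 (highest other 3425), at 150 mg/kg 1 of 100 reached 4637 (3414), between the doses 1 of 100 reached 1023 (753) and in liver 1 of 100 reached 2624 (281). The highest other lung splits kept 20 of 22 arrays with their real group, or put 0.857 of a group on 1 scan day, where the within-scan counts in the report apply. The shared direction of the doses was reached by 1 of 100 (3801, highest other 0).

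For microRNA 2 of 56 splits reached 18 at 300 mg/kg, few enough by the limit set beforehand to exclude chance for the count. The other split gave 90, more than the real one, and set control arrays 1 and 3 with array 1 at 300 mg/kg apart from the rest. This points to a structure of the samples, so the splits do not tie the 18 to the dose. At 150 mg/kg 6 of 56 splits reached 1 (highest other 74), so chance was not excluded. Between the doses the real count was 0, which all of 100 splits reach by construction (100 of 100, highest other 0), so these splits test nothing.

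For lists with a preset correlation chance was not excluded. As many lists as in the real split were called in 36 of 100 splits in lung at 300 mg/kg (18, highest other 27), 47 at 150 mg/kg (17, highest 29), 36 between the doses (16, highest 26), 16 in liver (15, highest 20) and 27 between tissues (13, highest 21). With an estimated correlation it was excluded in each by the limit set beforehand. Of 50 splits drawn only 1, the real one, reached 10 (highest other 0), 5 (1), 7 (1), 5 (0) and 2 (0). This concerns the number of lists called and not any single list.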

How the results depend on the processing

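The blocks for position on the slide, normexp fitted on all spots, quantile scaling of log ratios, the lower floor, lung median signals, the fits without sets of arrays and some scalings and blocks for lists were chosen only after the data were seen. The other alternatives were fixed before. The cause of a change below was not tested unless stated.

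Of the values of named genes under all alternatives, 1452 of 1459 in lung at 300 mg/kg kept direction and side of the threshold, 960 of 969 at 150 mg/kg, 524 of 550 between the doses, 1004 of 1014 in liver, 565 of 587 between tissues, and for microRNA 222 of 300, 156 of 180 and 206 of 210. Of list values the same was so for 904 of 936, 887 of 936, 825 of 897, 651 of 702 and 1108 of 1178, and no list that held with an estimated correlation lost its preset call when 1 array was left out.

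Counts moved by more than 1.5 times as follows. With median centring 4094, 2295 and 309 genes passed in lung at 300, at 150 and between the doses, 995 in liver (72.4% upward against 34.4%) and 1298 between tissues (28.4% upward against 56.5%), and it moved the median of all liver genes from -0.04 to 0.08. Requiring 1.5-fold left 1062, 472, 100, 845 and 1026 by construction. Between the doses Cy5 alone gave 620, normexp on all spots 597, array weights 1606, only the groups compared 658 and only titles 1 to 6 526 (fewer arrays). With the replicate number as a block 1547 genes passed between the doses, with the scan day block 1895. The position block gave 2790, 374 and 40, with 2702, 368 and 40 of them the same genes, and its larger standard errors (0.116, 0.161 and 0.111 against 0.065, 0.065 and 0.067) ended calls while the median absolute change of called genes was 0.33, 0.33 and 0.34 against 0.30, 0.28 and 0.31.

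For microRNA at 300 mg/kg normexp gave 219 (14.2% upward against 66.7%), the 75th percentile over all probes 79, quantile scaling 33, the scanner's total gene signal 8, the series values 58, the replicate block 1 and the slide block 39. Of the 18, these called 15 (normexp), 17 (75th percentile), 13 (quantile), 4 (total), 15 (series values) and 18 (slide block). At 150 mg/kg normexp gave 2, quantile scaling 25, the total gene signal 3, the series values 63, the lower floor 0 and the fit without control arrays 1 and 3 gave 9. Lists with an estimated correlation numbered 10, 5, 7, 5 and 2, and split controls gave 2445 genes shared by the doses.

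Leaving out each array in turn gave 5837 to 6195 genes in lung at 300 mg/kg, 4013 to 4832 at 150 mg/kg, 763 to 1345 between the doses, 2044 to 2571 in liver and 2588 to 3020 between tissues. For microRNA the ranges were 7 to 157 (157 without control array 6), 1 to 150 (150 without control array 6) and 0 to 1. Lists ranged from 16 to 18, 15 to 19, 15 to 21, 14 to 16 and 10 to 15.

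These values reversed. Between the doses Cyp1a1 was -0.11 with Cy5 alone. Nqo1 was -0.0599 with Cy5 alone, -0.0275 with quantile scaling of log ratios, -0.0230 with the scan day block, -0.00645 with the position block and -0.0732 with array weights. It was -0.0790 without array 5 at 300 mg/kg, -0.0574 without array 1 and -0.0352 without array 2 at 150 mg/kg, and at most 0.0821 with a single array left out. Liver Cyp1a2 was 0.15 with the scanner's log ratio, 0.72 with median centring, 3.66 with Cy5 alone and 0.11 as the mean of its probes, and Hsd3b5 was 0.0331 with the scanner's log ratio. Between tissues Cdkn1a was -0.0720 with the scanner's log ratio.

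MiR-34c* at 300 mg/kg was -0.26 with normexp and ranged from -0.0110 (without control array 6) to 0.0643 with a single array left out. MiR-34b-3p at 300 mg/kg was 0.0795 with the 75th percentile over all probes, 0.0863 with quantile scaling, 0.00518 with the series values and 0.36 without control arrays 1 and 3. At 150 mg/kg miR-34b-3p was 0.0129 with quantile scaling and 0.28 without control arrays 1 and 3. MiR-34c* was 0.0247 with the 75th percentile over all probes, 0.0846 with quantile scaling, 0.50 with the total gene signal, 0.14 with the series values, 0.0492 with the lower floor and 0.0608 without control arrays 1 and 3. Between the doses miR-34b-3p was -0.00864 with the total gene signal, -0.00184 with the slide block and -0.0145 without array 1 at 300 mg/kg.

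A scan day block was not run in liver, where each slide was its own scan. Quantile scaling of mean brightness leaves log ratios as they were by construction. Signal over background limits genes not well above background in control liver, whose folds are uncertain, and microRNAs at the floor.

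The replicate number paired no other groups: correlations of arrays with the same number ranged from -0.09 to 0.33 for 300 mg/kg and control, 0.05 to 0.42 for the doses and -0.35 to 0.62 in liver. With the replicate number as a random block across tissues, which may not be the same animal, 2900 genes differed between tissues (consensus correlation 0.0325).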

Other observations

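The genes of the next 2 paragraphs were chosen only after their values were seen, and they are given as values without an explanation. In lung at 300 mg/kg the gap junction genes Gja4 (-1.47 ± 0.171) and Gja5 (-1.93 ± 0.120), expressed in arteries, fell, and so did the arterial Sema3g (-1.34 ± 0.117) and the apelin receptor Aplnr (-1.56 ± 0.144), whereas Emcn, found in veins and capillaries, rose (0.96 ± 0.0790). Each kept its direction under every scaling at 300 mg/kg and within both scan days, while at 150 mg/kg Emcn (0.60) was -0.05 under one scaling. The fixed list of endothelial cells did not pass in lung at 300 mg/kg (1 of 20 rose, 4 fell). In liver Gja5 gave -0.23 (adjusted p 0.523) and Aplnr 0.13 (adjusted p 0.36).

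At 300 mg/kg the clock gene Per1 rose by 1.64 ± 0.277 in lung and 1.68 ± 0.182 in liver, and Per2 by 1.12 ± 0.124 and 0.68. Their output gene Dbp changed by -1.26 ± 0.161 in lung and -2.23 in liver, and the repressor Nr1d1 by -1.13 ± 0.184 and -2.25. The differences between tissues passed for Dbp (0.97) and Nr1d1 (1.12). These directions held under each scaling in both tissues and, in lung, within both scan days. As a list the clock passed in lung at 300 mg/kg with the preset correlation only (adjusted p = 0.202 with an estimated correlation), and in liver it did not pass (6 of 17 rose, 4 fell).

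A probe for the gammaherpesvirus microRNA mghv-miR-M1-2 was detected on all 13 microRNA arrays and changed by -0.50 at 300 mg/kg (adjusted p 0.0905). The cytomegalovirus microRNAs mcmv-miR-M23-1-5p (-0.14) and mcmv-miR-m88-1 (-0.08) were also detected on at least 3 arrays. Whether any of these signals came from viral RNA was not tested. The receptor gene Ahr itself fell in lung at 300 mg/kg (-0.54), while 9 of the 15 measured members of the target list, which includes Ahr, rose.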
